A study of Mus musculus with 10 samples.

How the data were processed

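The samples are polyA RNA-seq libraries from the ventral midbrain (substantia nigra pars compacta and ventral tegmental area) of naive mice of the strain Aldh1l1-NuTRAP. In such mice a tag on ribosomes is expressed in cells that use the Aldh1l1 promoter, which in brain is mostly astrocytes, and translating ribosome affinity purification (TRAP) pulls down the ribosomes with their RNA. Per the labels, 5 libraries hold input RNA of all cell types and 5 hold the purified astrocyte fraction, each built with the NEB Ultra II kit from 25 ng of total RNA. The sample titles carry the numbers 88, 92, 976, 981 and 982, each shared by 1 input and 1 astrocyte fraction library. The labels do not say whether these numbers are separate animals, so the p-values measure the spread between these samples.

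The authors deposited 1 table with 18464 genes that holds, for each library, estimated (expected) counts and a normalized log2 value. The expected counts as deposited are raw values per gene, not scaled by the authors, made from reads on the genome build mm10. They are not whole: between 4.94% and 31.1% of the values of a library lie within 0.001 of a whole number. The authors' normalized log2 values are centred on the input, with an input median of 0 for all 18464 genes. The submitters' processing notes name CASAVA 1.8, DESeq and the genome build mm10 without saying what each was used for. The aligner, the counting tool and the strand setting of the counting are not given in the sources used here, so counts of genes that overlap others on either strand are uncertain. Of the gene identifiers, 18430 are in GENCODE M21, and 17163 have identical coordinates there. Every gene in the table has at least 5 counts in all libraries of 1 or both groups, so the table had been filtered before it was deposited, and genes below that level cannot be assessed. The table holds 0 genes of the mitochondrial chromosome, so the list of mitochondrially encoded genes had no member to test.

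The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with a minimum count of 10, and the robust quasi-likelihood test. The filter kept 17672 genes and removed 792. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are astrocyte fraction minus input with a prior count of 2. Errors of log2 fold changes are standard errors computed from the log2 CPM (depth-scaled counts) of the 5 libraries of each group. They belong to the difference of mean log2 CPM. That difference can depart from the fitted log2 fold change where libraries vary widely, as for Crhr2. CPM values are given as mean ± SD over 5 libraries and use the TMM-scaled library size. Identifiers were kept apart for 21 repeated symbols.

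The comparison was also read through 27 gene lists written before the data were examined, of which 26 had members in the table. Each list was tested with camera (limma 3.58.1), which asks whether a list moved relative to all other genes, with a preset correlation between genes of 0.01 and with an estimated correlation. The fry test was run beside it and asks whether the genes of a list moved, on balance, in 1 direction. List p-values were adjusted over the 26 lists.

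The genes named were fixed by a rule. It takes every measured member of the CRF system list with Slc1a3, Slc1a2 and Aldh1l1. It takes the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes in the upper 50% by mean level whose groups do not overlap, leaving out pseudogenes and unnamed gene models. From each list it takes up to 3 called members with the smallest adjusted p in the direction of most called members and 1 in the other direction. The rule gave 113 genes, of which the values of 111 are reported and those of 2 were left out after the results were seen, for reasons unrelated to their values. Other genes named in the text were chosen after their values were seen, as were the gene families in the last part.

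The total of expected counts per library was 21812193 to 30878894 in the input, 24479136 to 26924406 in 4 astrocyte fraction libraries and 3845554 in the astrocyte fraction library 92. A count of 0 allows a level of up to 3 counts, which on the same CPM scale is 0.0912 to 0.125 CPM in the input, 0.880 CPM in the astrocyte fraction library 92 and 0.120 to 0.136 CPM in the other astrocyte fraction libraries. Such limits and the intervals of count ratios cover counting error only. Libraries of the same group had correlations of log2 CPM between 0.958 and 0.994, and the lowest chi-square per degree of freedom between libraries of a group was 11.5, above the value of 1 that repeat counting of 1 library gives. The common biological coefficient of variation was 0.229.

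The shared title numbers were checked as a pairing. After removal of each group's mean, libraries with the same number had correlations between 0.189 and 0.493, against a mean of -0.0791 for libraries with different numbers. The own partner was the best match for 4 of 5 input libraries and 4 of 5 astrocyte fraction libraries. The number is therefore used as a block in an alternative fit, while the comparison itself was designed without it.

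The pipeline was tested on simulated data with 17532 genes and 100 planted changes per size. edgeR recovered 70% of planted changes at a log2 of 1 and 93% at a log2 of 2, and 6.32% of its calls were false. With the block the recovery was 68% and 90% with 7.60% false calls, and DESeq2 1.42.0 recovered 80% and 96% with 20% false calls. In the same data camera called a planted list of 50 genes and did not call a random list of 49 genes. The planted changes were few, balanced in direction and without pairing, whereas most tested genes were called in the comparison itself. These rates may therefore not carry over to it.

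Alternatives were DESeq2 size factors, scaling to total counts, the DESeq2 Wald test, no filter, a filter at a mean of 5 CPM, a prior count of 5, the title number as a replicate block, and leaving out each library and each number in turn. A fit without the numbers 976 and 982 and a limma-trend fit of the authors' normalized log2 values were added after the data were examined. Overlaps of exons were taken from GENCODE M21, and matches of pseudogenes to mitochondrial transcripts were found with blastn 2.17.0 at 95% identity or more over at least 80 bases. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The raw reads were not used.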

Results

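RNA was measured in 10 libraries from the ventral midbrain of naive Aldh1l1-NuTRAP mice, 5 of input RNA from all cell types and 5 of the astrocyte fraction, in which RNA is pulled down on the tagged ribosomes of cells that use the Aldh1l1 promoter. The total of expected counts per library ran from 21812193 to 30878894 in the input. It was 3845554 in the astrocyte fraction library 92 and 24479136 to 26924406 in the other 4 astrocyte fraction libraries. In that library 1713 genes of the table had no count, against 249 to 359 in the other astrocyte fraction libraries. The 10 most abundant genes took 3.38 ± 0.175% of the counts in the input (SD, n = 5) and 9.31 ± 1.39% in the astrocyte fraction (SD, n = 5). The series concerns CRF receptor 2, encoded by Crhr2, and the glutamate transporter GLAST, encoded by Slc1a3, in relation to psychostimulants. These libraries come from animals without drug, so the comparison of fraction with input asks which transcripts midbrain astrocytes hold on their ribosomes and whether both genes are among them.

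Most tested transcripts differed between astrocyte fraction and input, and the marker lists of different cell types moved in different directions. Most listed astrocyte markers, genes of ion, water and gap junction homeostasis and genes of fatty acid oxidation were higher in the astrocyte fraction. All listed pan-neuronal, mature oligodendrocyte and microglia markers were lower. Slc1a3 was about as enriched as the astrocyte marker Aldh1l1, whereas Crhr2 was low in both groups and was not called. Of 17672 tested genes, 5858 were higher and 6625 lower in the astrocyte fraction, and 5189 were not called. At 2-fold or more, 2854 genes were higher and 4297 lower. The higher genes made up 46.9% of the called genes with TMM scaling, 34.0% when libraries were scaled to their total counts, and 50.03% without the numbers 976 and 982. Total count scaling moved the median log2 fold change of all genes from -0.06 to -0.34, which lowers every fold change by about the same amount.

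Nearly all astrocyte markers rose. Of 28 markers tested, 27 were higher, 0 lower and 1 not called, and the count was also 27 when adjusted over the list alone. Their median log2 fold change was 3.04, an 8.24-fold enrichment (camera adjusted p = 2.35e-35, and 0.0324 with an estimated correlation). Aldh1l1 (ENSMUSG00000030088, mm10 chromosome 6, 90486427 to 90600203), which encodes a folate enzyme and drives the tag, rose from 99.6 ± 7.65 to 814 ± 92.3 CPM (SD, n = 5), a log2 fold change of 3.03 ± 0.09 (SE, adjusted p = 7.08e-11). Slc1a3 (ENSMUSG00000005360, chromosome 15, 8634124 to 8710764) rose from 272 ± 57.4 to 2267 ± 645 CPM, a log2 fold change of 3.06 ± 0.25 (adjusted p = 1.72e-07). Slc1a2, which encodes the other main astrocyte glutamate transporter (chromosome 2, 102658659 to 102790784), rose from 1161 ± 122 to 8458 ± 1840 CPM, a log2 fold change of 2.86 ± 0.15. The tight junction gene Cldn10 (3.39), the membrane protein gene Mlc1 (3.16) and the glycogen regulator Ppp1r3c (3.21) had the smallest adjusted p-values of the list. The marker not called was Hapln1, which encodes a matrix link protein (log2 fold change 0.15, adjusted p = 0.407).

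Most measured genes of the CRF system were lower in the astrocyte fraction. Of its 5 genes in the table, 0 were higher, 4 lower and 1 not called, with the same 4 lower when adjusted over the list alone. The list's median log2 fold change was -2.22 (camera adjusted p = 0.278). Crhr1, the gene of CRF receptor 1, fell from 15.03 ± 3.07 to 2.67 ± 1.37 CPM, a log2 fold change of -2.34 ± 0.49 (adjusted p = 7.10e-06). Crh, which encodes the peptide itself, fell from 2.52 ± 1.75 to 0.415 ± 0.253 CPM, with a log2 fold change of -2.33 ± 0.46. Crhbp, the gene of the CRF binding protein, had a log2 fold change of -2.22 ± 0.85 (adjusted p = 0.000315). The urocortin gene Ucn had a log2 fold change of -1.63 ± 0.81 (adjusted p = 0.0349). That call was lost when any of 6 libraries was left out, the inputs 88, 976 and 982 and the astrocyte fraction libraries 92, 976 and 981, with adjusted p from 0.0645 to 0.0773. Ucn2 and Ucn3 are not in the table.

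Crhr2 (ENSMUSG00000003476, chromosome 6, 55090049 to 55133016) was at 1.37 ± 1.58 CPM in the input and 3.24 ± 5.71 CPM in the astrocyte fraction (SD, n = 5), a log2 fold change of 1.27 ± 1.31 (adjusted p = 0.355). It was higher in the astrocyte fraction in 3 of 5 numbers. Most of its signal came from number 976, with 4.05 CPM in the input and 13.4 CPM in the astrocyte fraction, from 110 and 336 counts. The astrocyte fraction libraries 88, 92 and 981 held 13, 2 and 1 counts. Without the astrocyte fraction library 976 its log2 fold change was -0.79 (adjusted p = 0.461), and without the numbers 976 and 982 it was -0.81 (adjusted p = 0.424). The same numbers carried transcripts of the choroid plexus, the tissue that makes cerebrospinal fluid. Ttr, the transthyretin gene, was at 2965 and 604 CPM in the inputs 976 and 982 and at 11036 and 2312 CPM in their astrocyte fraction libraries, against 0.334 to 11.5 CPM in the other libraries. The direction of Crhr2 therefore depends on these libraries and could not be settled at this number of samples.

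**Figure D1:**
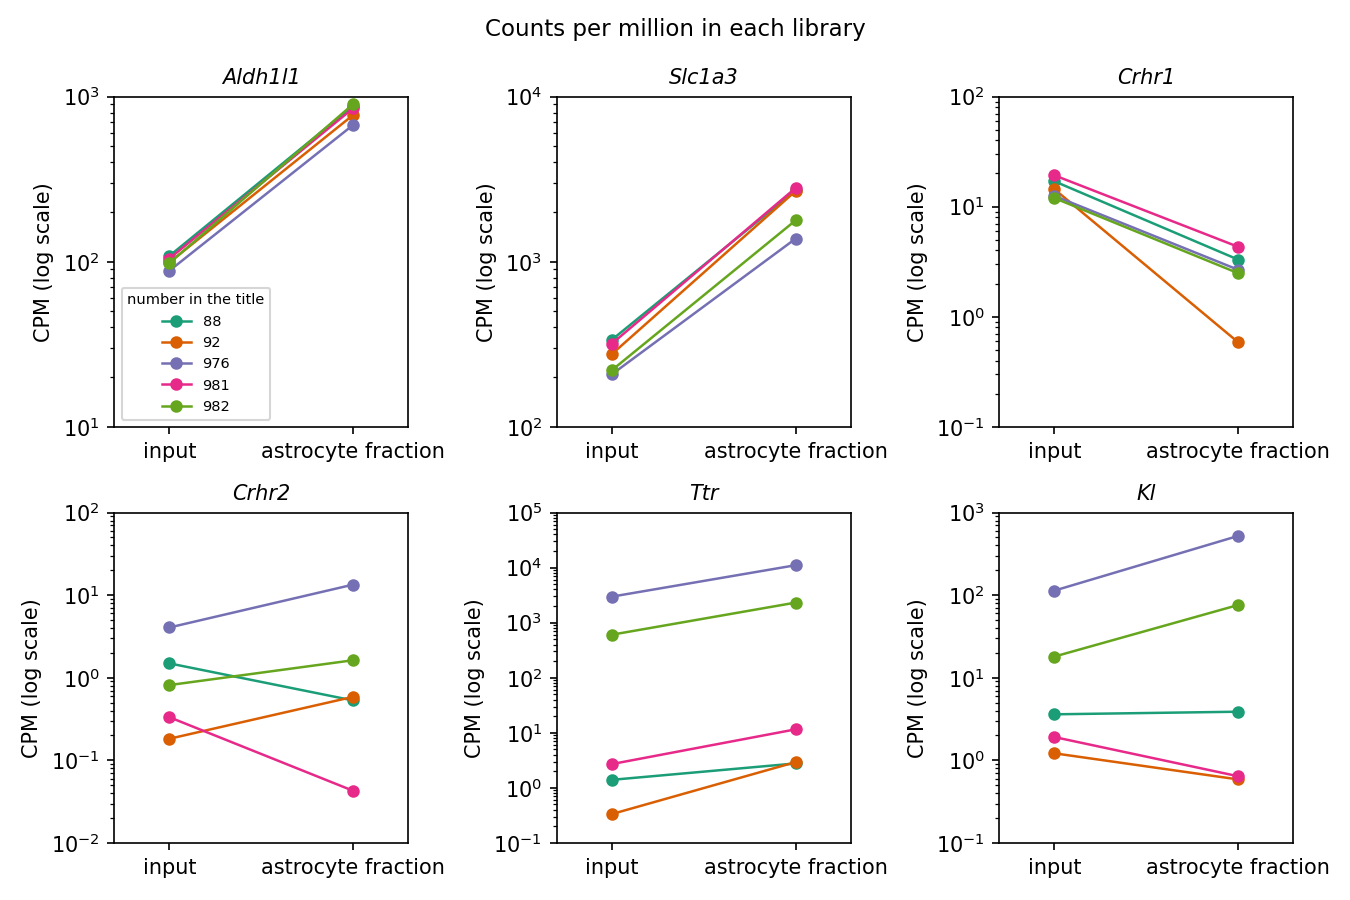
CPM on a log axis for Aldh1l1, Slc1a3, Crhr1, Crhr2, Ttr and Kl in each of the 10 libraries, with a line joining the input and astrocyte fraction library of the same number. Aldh1l1 and Slc1a3 are higher in the astrocyte fraction in 5 of 5 numbers, Crhr1 in 0 of 5 and Crhr2 in 3 of 5, and Crhr2 is highest in number 976, where Ttr and Kl are also highest.

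The 12 genes with the largest gains included the astrocyte marker Cldn10 given above. The others were led by Olfr287 (log2 fold change 3.69), the mitochondrial carrier Slc25a34 (3.54), the potassium channel subunit Kcne1l (3.47), the glutathione transferase Gstt3 (3.46), the chemokine Cxcl14 (3.43) and the Notch feedback gene Nrarp (3.42). The sphingosine receptor S1pr1 rose from 125 ± 7.60 to 1319 ± 179 CPM, a log2 fold change of 3.40 ± 0.10 (adjusted p = 6.49e-11). Nat8f3, Eva1a, Mmd2 and the homeobox gene Dbx2 each had a value of 3.38. Olfr287 shares 10.7% and Gstt3 13.6% of their exon bases with another gene model on their own strand, and Nrarp shares 79.4% with an antisense one, so their counts are uncertain. Csf1r, Alas2, Aldh1l1 and Cox6a2 share between 10.3% and 15.1% with a gene on the opposite strand. The 12 largest losses were led by Lrrc17, which fell from 41.9 ± 10.1 to 1.31 ± 1.61 CPM (log2 fold change -5.56 ± 0.69). Microglial genes followed, with the protease Ctss (-5.05), the complement genes C1qc (-4.73), C1qa (-4.34) and C1qb (-4.29) and the receptor Csf1r (-4.68). The neuronal RNAs Mir124a-1hg (-5.00) and Snhg11 (-4.46) and the myelin genes Ugt8a (-4.13), Myrf (-4.03), Mag (-3.99) and Mog (-3.98) completed the group.

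Neuronal transcripts were depleted about 5-fold at the list medians. All 18 pan-neuronal markers were lower (also 18 when adjusted over the list alone), with 20.4% of the input level retained at a median log2 fold change of -2.29 (camera adjusted p = 5.33e-18). The tubulin gene Tubb3 (-2.57), the enolase gene Eno2 (-2.42) and the vesicle gene Rab3a (-2.20) had the smallest adjusted p-values. All 10 GABA neuron markers were lower (10 when adjusted over the list alone), with a median of -2.16 (camera adjusted p = 0.00166). Of the 10, 8 were lower without the numbers 976 and 982 and 9 without the astrocyte fraction library 92. Among them, Gad1, which encodes the enzyme that makes GABA, fell by 2.48 and the interneuron gene Pvalb by 2.46 on the log2 scale. Of 15 dopamine neuron markers, 14 were lower and 1 higher, and the counts were the same when adjusted over the list alone. Their median was -2.36, but the list was not called against all other genes (camera adjusted p = 0.143). It was called with the title number as a block (adjusted p = 5.00e-08) and without number 981 (adjusted p = 0.0255). The block call was lost at adjusted p = 0.0871 with an estimated correlation. The transcription factor gene Nr4a2 (-2.31), the receptor gene Drd2 (-2.36) and the nicotinic subunit Chrnb3 (-2.60) were lower. The exception was Aldh1a1, a retinaldehyde dehydrogenase gene, which rose from 297 ± 77.9 to 1778 ± 181 CPM (log2 fold change 2.58). Of 7 measured glutamate, acetylcholine and serotonin neuron markers, 0 were higher, 5 lower and 2 not called, and 6 were lower when adjusted over the list alone. This list had a median of -2.47 and was not called (camera adjusted p = 0.215) except with the block (adjusted p = 0.0170), a call lost at adjusted p = 0.295 with an estimated correlation. The vesicular glutamate transporters Slc17a6 (-2.44) and Slc17a8 (-2.54) and the choline transporter Slc5a7 (-3.33) were among the lower genes.

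Oligodendrocyte and microglial transcripts had lower medians than neuronal ones. All 14 mature oligodendrocyte markers were lower (14 when adjusted over the list alone), with 7.59% retained at a median log2 fold change of -3.72 (camera adjusted p = 8.59e-20), and 13 were lower without the numbers 976 and 982. Myrf, which encodes a regulator of myelin genes, fell from 113 ± 6.92 to 6.87 ± 1.16 CPM (log2 fold change -4.03). All 14 microglia markers were lower (14 when adjusted over the list alone), with 5.40% retained at a median of -4.21 (camera adjusted p = 2.11e-12). Tmem119, a membrane protein gene of resident microglia, fell by 4.17 on the log2 scale. Of 9 precursor and lineage markers, 7 were lower and 2 higher, with the same counts when adjusted over the list alone and a median of -3.17 (camera adjusted p = 0.00509). That call was lost at adjusted p = 0.164 with an estimated correlation. Sox10 (-3.48), Gpr17 (-3.21) and Vcan (-3.73) were lower, whereas the transcription factor genes Olig1 (1.58) and Olig2 (0.86) were higher.

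All red blood cell markers were lower, whereas most ependymal and many endothelial markers were not called. Of 11 endothelial markers, 1 was higher, 5 were lower and 5 were not called, with a median log2 fold change of -0.24 and 84.9% of the input level retained (camera adjusted p = 0.833). The glucose transporter Slc2a1 rose by 1.31 on the log2 scale. Esam, an endothelial adhesion gene, fell by 0.71. Itm2a (-0.42) and Kdr (-0.71) were also lower. The Itm2a call was lost without the astrocyte fraction library 976 (adjusted p = 0.0668), and the Kdr call without that library (0.0559) or the astrocyte fraction library 981 (0.0513). Scaled to total counts, 8 endothelial markers were lower and 1 higher, and without the numbers 976 and 982, 2 were lower and 1 higher. Of 11 mural and fibroblast markers, 2 were higher, 8 lower and 1 not called, with a median of -1.41 (camera adjusted p = 0.439). Without the numbers 976 and 982, 2 were higher and 5 lower. The pericyte gene Rgs5 (-1.57), the smooth muscle gene Myh11 (-1.95) and the channel gene Kcnj8 (-1.66) were lower, and the collagen gene Col1a2 (1.28) was higher. Of 7 measured ependymal and choroid plexus markers, 1 was higher, 0 lower and 6 not called, with a median of 1.63 (camera adjusted p = 0.760). With the block, 3 were higher and 2 lower, and without the astrocyte fraction library 976 the median was -0.19. The called marker was the chemerin gene Rarres2 (1.63), which shares 33.6% of its exon bases with a gene on the opposite strand. All 5 red blood cell markers were lower, with a median of -2.53, and the list was not called (camera adjusted p = 0.215) except with the block (0.000149) or without number 88 (0.00670). The block call was lost at adjusted p = 0.209 with an estimated correlation. The haem enzyme gene Alas2 fell by 2.39 on the log2 scale. The globin genes Hba-a1 (-2.59) and Hbb-bs (-2.76) have near-identical copies, so their separate counts are uncertain.

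Genes of glutamate handling went both ways. Of 14 genes, 7 were higher and 7 lower, with the same counts when adjusted over the list alone, a median log2 fold change of 0.43 and no call for the list (camera adjusted p = 0.323). Glul, whose glutamine synthetase converts glutamate to glutamine, rose from 1664 ± 71.4 to 8907 ± 1347 CPM (2.42 ± 0.10). The glutamine transporter Slc38a3 rose by 2.81 and the glutamate dehydrogenase gene Glud1 by 2.22, while the aminotransferase gene Got1 fell by 1.88 on the log2 scale. Transmitter and drug-related receptors also went both ways, with 11 of 25 higher, 11 lower and 3 not called. Their median (-0.10) and mean (-0.12) were negative while the set test pointed up without a call (camera adjusted p = 0.215). The median turned positive without the input library 88 (0.26), the input library 92 (0.03) or the astrocyte fraction library 976 (0.01). The adenosine receptor Adora2b (3.35), the endothelin receptor Ednrb (3.14) and the adrenergic receptor Adra2a (2.42) were higher, and the metabotropic glutamate receptor Grm5 (-1.67) was lower.

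Most genes for ion and water handling, gap junctions and synapse modulation were higher. Of 12 ion, water and gap junction genes, 10 were higher, 1 lower and 1 not called, with a median log2 fold change of 3.01, or 8.08-fold (camera adjusted p = 7.33e-11). The connexin genes Gjb6 (3.20) and Gja1 (3.05) and the potassium channel gene Kcnj16 (3.21) led, and the sodium-calcium exchanger Slc8a1 (-1.84) was lower. Of 13 synapse-modulating and phagocytic genes, 10 were higher, 0 lower and 3 not called, with a median of 1.85 (camera adjusted p = 2.39e-05). The glypican Gpc5 (2.96), the thrombospondin Thbs2 (2.65) and the matrix gene Sparc (2.90) were among them.

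Most tested genes of 4 metabolic lists were higher, and fatty acid oxidation had the highest median of the 4. Of 18 fatty acid oxidation genes, 17 were higher and 1 lower, with the same counts when adjusted over the list alone and a median log2 fold change of 2.26, or 4.80-fold (camera adjusted p = 6.08e-21). Cpt1a, which encodes the enzyme that admits fatty acids to mitochondria, rose from 33.1 ± 2.86 to 228 ± 5.01 CPM (2.78 ± 0.06). Hadhb (2.52) and Acadm (2.33) rose as well, and the acyl-CoA synthetase gene Acsl1 (-1.60) was lower. Of 20 glycogen, glycolysis and lactate genes, 13 were higher, 2 lower and 5 not called, with a median of 0.88 (camera adjusted p = 1.87e-06). Scaled to total counts, 13 were higher and 5 lower. The aldolase gene Aldoc (2.65) and the glycogen synthase gene Gys1 (1.87) rose, and the lactate exporter Slc16a3 fell by 2.29. Of 19 cholesterol biosynthesis genes, 14 were higher, 1 lower and 4 not called, with a median of 0.48 (camera adjusted p = 0.0143). That list call was lost with adjusted p = 0.525 with an estimated correlation and at 0.0764 with the filter at a mean of 5 CPM. Scaled to total counts, 10 were higher and 5 lower with a median of 0.19. Msmo1 (1.47), Mvd (1.13) and Sc5d (1.07) were higher. Of 77 nuclear-encoded respiratory chain genes, 67 were higher, 2 lower and 8 not called, with a median of 0.67 (camera adjusted p = 1.21e-07; adjusted p = 0.525 with an estimated correlation). Ndufa7 (1.22) and Uqcrfs1 (1.16) rose, as did the succinate dehydrogenase gene Sdhc with a 3.49-fold gain, whereas Cox6a2 (-3.01) fell.

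Most Notch, BMP and Shh pathway genes were higher and most immediate early genes lower. Of 20 Notch, BMP and Shh pathway genes, 17 were higher, 2 lower and 1 not called, with a median log2 fold change of 2.05 (camera adjusted p = 4.12e-10). The hedgehog receptor Ptch1 (2.90), the BMP receptor Bmpr1a (2.50) and the inhibitor Id2 (3.24) rose, and Hhip, which binds hedgehog outside the cell, was lower (-1.43). Of 18 measured reactive astrocyte genes, 10 were higher, 1 lower and 7 not called, with a median of 0.61 and no call for the list (camera adjusted p = 0.379). With libraries scaled to total counts, 5 were higher and 1 lower. The protease inhibitor Serpina3n (1.47), Aspg (1.46) and Fbln5 (2.14) were higher and Fkbp5 (-1.47), a glucocorticoid response gene, was lower. Of 14 measured immediate early genes, 0 were higher, 11 lower and 3 not called, with a median of -1.48 (camera adjusted p = 0.0119; adjusted p = 0.407 with an estimated correlation). Arc (-2.63), Egr1 (-2.36) and Fos (-1.44), which neurons induce on firing, were lower.

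RNAs that stay in the nucleus were listed as a control of the ribosome purification. All 9 nuclear long noncoding RNAs were lower (9 when adjusted over the list alone), with 10.4% retained at a median log2 fold change of -3.27 (camera adjusted p = 1.22e-08). The imprinted RNAs Rian (-3.59), Peg13 (-1.60) and Kcnq1ot1 (-1.70) were among them. The list also holds Snhg11, named above as a neuronal RNA. Whether these RNAs fell because they are nuclear or because neuronal RNA was depleted was not tested. Of 87 cytosolic ribosomal protein genes, 23 were higher, 15 lower and 49 not called with a median of 0.04 (camera adjusted p = 0.395), a direction that flips when libraries are scaled to total counts, where 7 were higher and 37 lower with a median of -0.24. Rpl10a (2.27), Rpl22 (1.05) and Rpl7l1 (1.03) were higher and Rpl22l1 (-0.67) was lower under TMM scaling.

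The counts adjusted over the list alone equalled those over all tested genes for every list but the glutamate, acetylcholine and serotonin list given above and the ribosomal list, with 22 higher and 14 lower under TMM scaling, where total count scaling flips the direction. Across the 26 lists, camera called 8 up and 7 down with the preset correlation and 11 with an estimated one. The 4 calls lost were those of the oligodendrocyte precursor, cholesterol, respiratory chain and immediate early lists. The 11 calls kept were much weaker with the estimated correlation, with camera adjusted p from 0.0124 (fatty acid oxidation) to 0.0467 (microglia). The astrocyte and pan-neuronal lists were both at 0.0324 and the mature oligodendrocyte list at 0.0149. With both the block and an estimated correlation the smallest adjusted p was 0.0781, that of the mature oligodendrocyte list.

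**Figure D2:**
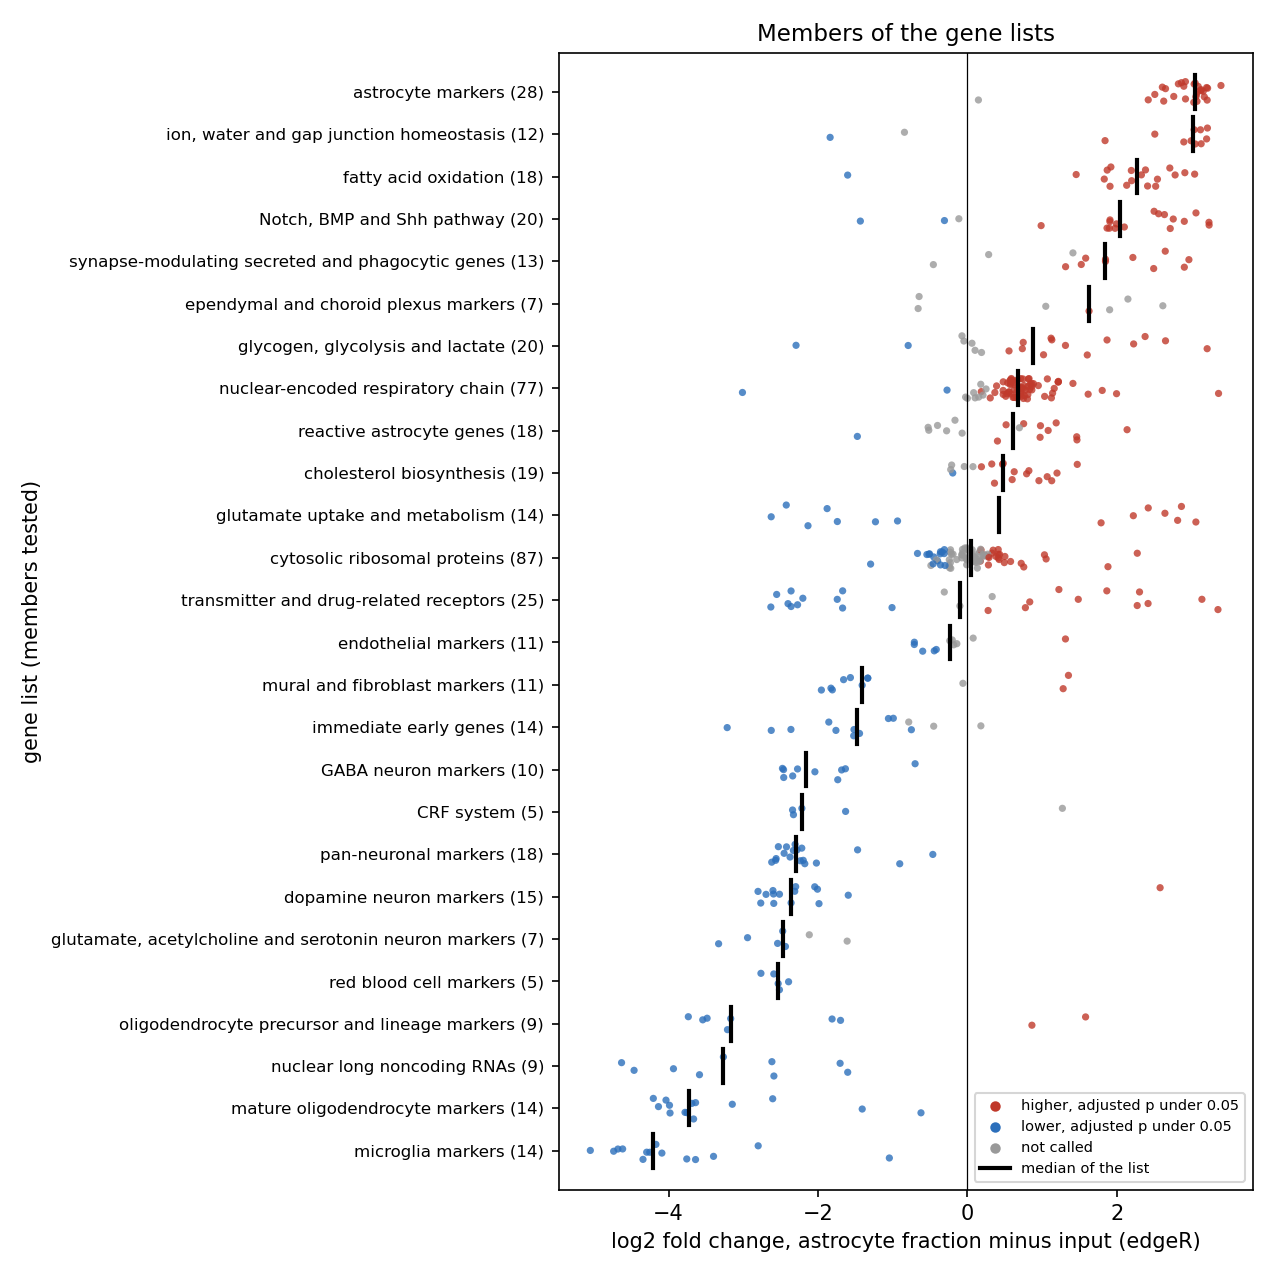
Log2 fold change (astrocyte fraction minus input) of each tested member of 26 gene lists, ordered by list median, with higher genes in red, lower genes in blue, genes not called in grey, the median as a black bar and the number tested in brackets. Astrocyte markers lie near a median of 3.04 and microglia markers near -4.21, and ribosomal proteins lie near 0.04, a sign that flips to -0.24 when libraries are scaled to total counts.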

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

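The split tests, the depth test of library 92, the tests of vessel cells and of spread among endothelial markers, and the test of pseudogenes in general were set before their results were seen; the tests of choroid tissue, carry-over and tagged cells for Crhr2, of equal carry-over for endothelial genes and of mitochondrial matches were chosen only after the result was seen. Chance was examined by refitting edgeR to 100 splits of the 10 libraries into 5 and 5. Only the real split, 1 of 100, gave as many calls, with 5858 higher and 6625 lower genes against a highest count of 0 in any other split. The counts at 2-fold or more, 2854 higher and 4297 lower, were also reached by 1 split of 100, against a highest other of 0. The 12 other splits that part all 5 pairs, as the real one does, gave a highest count of 0 as well, and they differ from it in mixing input and astrocyte fraction on each side. Such mixing puts the difference between the fractions into the spread within each side, which works against calls there. The counts of 0 in the other splits therefore cannot exclude chance by themselves. The splits that part all 5 pairs are also too few to give a small probability.

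The Crhr2 level of 13.4 CPM in the astrocyte fraction library 976 lay far above the other 4 astrocyte fraction libraries, at 0.0428 to 1.63 CPM. Low depth of library 92 is argued against only as the reason for the missing call, since leaving it out moved the log2 fold change by 0.20 and gave no call (adjusted p = 0.324). That test cannot bear on the high level in library 976, which is a separate library. Choroid plexus tissue in the dissections numbered 976 and 982 may account for much of the signal: the ratio of Crhr2 between astrocyte fraction libraries 976 and 982 was 8.23 (95% exact binomial interval 5.83 to 11.95), which overlaps the 4.77 to 6.86 of Ttr, Kl and Aqp1. Simple carry-over of choroid RNA without the tag is argued against, because those 3 genes were higher in the astrocyte fraction by a mean log2 ratio of 2.16 (SD 0.26) within these numbers, so expression of the tag in choroid cells stays open and was not tested. Whether tagged cells hold most Crhr2 transcripts in numbers 88, 92 and 981 stays open. The pooled ratio of astrocyte fraction to input was 0.448 from 16 and 62 counts, with an interval below 1 (0.241 to 0.787). The ratios were 0.356 (0.177 to 0.667) in 88, 0.129 (0.0029 to 0.959) in 981 and 3.22 (0.318 to 17.997) in 92. The pooled value rests mostly on the 13 counts of the astrocyte fraction library 88. Libraries 981 and 92 held 1 and 2 counts, near the limit of detection.

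Endothelial markers were depleted less than markers of other cells without the tag. Equal carry-over of RNA from every untagged cell type would give equal medians. The endothelial median log2 fold change lay 3.64 above that of 28 microglia and mature oligodendrocyte markers (permutation p = 2e-05). This difference restates the pattern, which was seen before the test, so it is no separate support. The permutations here also treat the genes of a list as independent. Retention of vessel cells as a whole stays open, since mural and fibroblast markers also lay above that reference, by 2.47 (permutation p = 0.00014). Endothelial markers lay a further 1.17 above the mural and fibroblast ones (permutation p = 0.015). Each of these lists holds a gene that rose, Slc2a1 and Col1a2, so this difference between lists does not show how vessel cells were retained. Expression of some of the markers by astrocytes themselves was not settled, as the SD of the endothelial members was 0.553 times that of the microglia members (permutation p = 0.48). A biological explanation was not tested.

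Pseudogenes that match mitochondrial transcripts fell together, although the table holds no gene of the mitochondrial chromosome. The 11 pseudogenes summed to 17275 ± 1040 CPM in the input and 1121 ± 126 CPM in the astrocyte fraction (SD, n = 5), and each of the 11 was lower. Their median log2 fold change lay -4.20 from that of the other pseudogenes, which restates the fall and is no separate support. Gm28439, Gm28437, Gm10925 and Gm28661 match mt-Nd4, mt-Co3, mt-Atp6 and mt-Co2 at 100% identity over 678 to 876 bases. Reads within these stretches cannot be told apart from reads of the mitochondrial transcripts. These counts are therefore no measure of pseudogene expression. How many reads came from mitochondrial transcripts stays open. A loss of pseudogene reads in general is argued against by the median of 0.16 over the 1590 pseudogenes without such a match.

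Of 224 groups of 5 libraries examined, 22 had 1 library far from the other 4, where about 1 in 20, or 11.2, arise by chance. The astrocyte fraction library 92 had a total of 3.85 M counts against 24.5 M to 26.9 M. It was also the highest of its group for Lrrc17 (4.11 CPM), Tubb3 (108 CPM), Slc17a6 (99.2 CPM), Slc8a1 (13.5 CPM) and Kcnq1ot1 (73.1 CPM). The input library 88 was the highest for C1qa (63.1 CPM), Tmem119 (24.9 CPM), Alas2 (11.4 CPM), Hba-a1 (244 CPM) and Hbb-bs (149.6 CPM). Input 92 was the highest for Slc1a2 (1372 CPM) and the lowest for Aldoc (1054 CPM). Input 982 was the lowest for S1pr1 (112 CPM), and input 981 was the highest for Sc5d (79.5 CPM). In the astrocyte fraction, library 88 was the highest for Crh (0.857 CPM) and library 982 for Olig1 (945 CPM). Library 981 was the highest for Nr4a2 (11.1 CPM) and Chrnb3 (7.61 CPM). Library 976 was the lowest for Gjb6 (511 CPM) and Ptch1 (773 CPM).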

How the results depend on the processing

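The tests of the comparison and of the lists, the gene lists, the named-gene rule and all alternatives but 2 were set before the data were examined; the fit without the numbers 976 and 982 and the limma fit of the authors' log2 values were added afterwards. Over the 24 alternatives with gene tests, 105 of 108 reported named genes besides the 3 study genes of the design kept their direction and, where tested, their side of the threshold. Over the 22 with list tests at the preset correlation, 21 of 26 lists kept the direction and call of camera. The medians of 3 lists without a call changed sign: ribosomal proteins (-0.24 with total count scaling and -0.03 with the filter at a mean of 5 CPM), receptors (up to 0.27 without replicate 88) and ependymal and choroid markers (-0.19 without the astrocyte fraction replicate 976). Leaving out each library or number gave 5354 to 6130 higher and 6122 to 6901 lower genes, and Slc1a3 stayed between 2.98 and 3.26 and Aldh1l1 between 2.99 and 3.16. The filter at a mean of 5 CPM tested 12149 genes against 17672. It gave 2635 genes at least 2-fold lower against 4297, and 1991 at least 2-fold higher against 2854. Crhr2 ranged from -0.79 without the astrocyte fraction replicate 976 to 2.15 without the input replicate 976 and was -0.81 without the numbers 976 and 982; its adjusted p ran from 0.155 to 0.998, it was called in no alternative, and library 976 holds most of its counts. The fry test called 23 lists against 15, since it does not compare a list with other genes, and the estimated correlation left 11. The title number as a replicate block gave 5885 higher and 6843 lower genes, of which 5732 and 6516 were called without it, and changed no other call of a named gene or list than the 3 given in the report. Total count scaling gave 4293 higher and 8317 lower genes, since it moves every fold change down, and it changed no call of a named gene or list test. The authors' log2 values gave 5638 and 6798, and Ucn was then not called (adjusted p = 0.0726); the cause was not tested. Without the numbers 976 and 982 the dopamine neuron and glutamate lists were called (adjusted p = 0.00742 and 0.0379). Depth limits genes near 1 CPM most in the astrocyte fraction library 92.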

Other observations

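The gene families and genes in this part were chosen after their values were seen, and no explanation was tested for them. The tag of this strain rests on a ribosomal protein L10a fusion and a RanGAP1 fusion, and both genes rose. Rpl10a went from 141 ± 16.8 to 682 ± 20.6 CPM (log2 fold change 2.27 ± 0.08) and Rangap1 from 527 ± 63.6 to 2164 ± 183 CPM (2.04 ± 0.10, adjusted p = 1.49e-09). The counts do not separate transgene from endogenous transcripts.

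Of 18 glutathione S-transferase genes, 12 were higher and 1 lower with a median log2 fold change of 1.49. Of 9 genes of the N-acetyltransferase 8 family, 8 were higher and 1 lower with a median of 2.87. Wnt receptors of the Fzd family had 8 of 10 genes higher and 0 lower (median 1.38). Of 78 mitochondrial ribosomal protein genes, 57 were higher and 4 lower with a median of 0.43. With libraries scaled to total counts 31 were higher and 10 lower, with a median of 0.14.

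All 11 sodium channel subunit genes were lower (median -2.37). Of 15 GABA-A receptor subunits 12 were lower and 3 higher (median -2.02), and the highest was Gabrg1 at 2.30. Of 16 AMPA, kainate and NMDA receptor subunits 11 were lower and 3 higher (median -1.31), and the highest was Grin2c at 1.74. Of 16 synaptotagmins 12 were lower and 2 higher (median -1.92), and of 20 semaphorins 13 were lower and 3 higher (median -1.18). Among noncoding genes, 245 of 469 lincRNAs were lower and 104 higher (median -0.85), and 19 of 23 sense intronic RNAs were lower and 1 higher (median -2.60). Whether easier entry of weakly expressed genes through the input adds to these lower counts was not tested.

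The input libraries differed in regional genes. In the order 88, 92, 976, 981 and 982, Th was at 161, 229, 65.5, 310 and 75.6 CPM and Slc6a3 at 226, 341, 83.6, 497 and 86.4 CPM. In the same order the cortical and pontine transporter gene Slc17a7 was at 74.3, 198, 408, 74.5 and 370 CPM. Tph2, a listed serotonin neuron marker, was at 1.49, 1.37, 30.7, 0.249 and 6.48 CPM in that order. The inputs 976 and 982, whose numbers carried the choroid plexus transcripts, had the lowest Th and Slc6a3 and the highest Slc17a7 and Tph2. These values were not tested.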
